A study of Oryza sativa with 8 samples.

How the data were processed

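Gene expression in rice leaves (Oryza sativa cv. Nipponbare) was measured on 8 two-colour Agilent arrays. Each array carried wild-type RNA in the Cy3 channel and RNA of the rerj1 mutant in the Cy5 channel, both taken at the same time after wounding, per the labels. The times were 0, 30, 60 and 120 min with 2 biological replicates each, so that the 8 arrays fell into 4 groups of 2. The series describes the mutant as carrying a Tos17 insertion, Tos17 being a rice retrotransposon used for gene tagging. Total RNA was extracted with a column kit and amplified and labelled with a linear amplification kit, per the labels' protocols. The dyes were not swapped on any array, so a ratio of mutant over wild type contains any difference between the dyes at that probe. A change over time within one channel contains none. No unwounded plants were kept to the later times among the samples analysed here, so that wounding and time of day cannot be told apart.

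The arrays were scanned and read with Agilent Feature Extraction 10.5.1.1 on array design 015241, per the file headers. The deposited files give, for each spot, the mean intensity of both dyes and the median intensity of the local background, neither of them corrected. They also hold processed intensity values that Feature Extraction had background-subtracted and dye-normalised within the array, and a log10 ratio of Cy5 over Cy3 made from these, per the file headers. The deposited value table of the series holds the same log10 ratio, mutant over wild type, to 3 significant digits. Its columns had a median of 0 on every array and were compared with the scanner values of the same array by feature number, so that its scale and direction are known. Flags for saturation, for outlier spots and for signals well above background came from the same files.

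From the uncorrected intensities, the background was corrected with the normexp method and an offset of 50 in limma 3.58.1 under R 4.3.3. The dyes of each array were normalised with loess, with control spots given no weight, and the mean intensities of the arrays were then made equal in distribution (Aquantile). Of 45151 features per array, 1417 control spots were left out after the background step, and 1610 further spots without a rice locus, among them probes for microRNA precursors, were left out of the gene tests. Spots marked as outliers (52 to 95 per array) were set to missing, and no spot was saturated. Replicate spots of a probe were averaged. A probe was kept where it was well above background in both replicates of at least 1 combination of genotype and time, which 32936 of 41908 probes were. The brightest probe stood for each of the 22629 genes tested, out of 29695 loci on the array; 6529 of these had several probes past the filter. Gene names are those of the array's annotation by locus of the Rice Annotation Project, which can be old, and no coordinates were used here. A probe below background throughout one of the groups compared has only a bound there, given as at least N-fold: the brighter mean against, per array, the higher of the dim probe's own signal and the lowest signal of any probe well above background. These bounds are open to dye bias where the groups lie in different channels.

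Depth has no counterpart on arrays; the number of arrays limits the precision, with 4 residual degrees of freedom per gene. Linear models were fitted to all 8 arrays with limma (lmFit and eBayes), separately to the Cy3 values, the Cy5 values and the log2 ratios. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 change of 1 or more. The comparisons were wild type at 30, 60 and 120 min against 0 min, the mutant likewise, mutant over wild type at each of the 4 times, the change of that ratio from 0 min, and a moderated F test of any change of the ratio over time. Genes dependent on RERJ1 were defined as those that rose in wild type and whose ratio fell from 0 min at the same time. Errors of log2 changes are standard errors of the model unless SD is written, and every change rests on 2 arrays per time.

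For 33 gene lists, fixed before the data were examined like the comparisons, thresholds and alternatives, the camera test of limma asked whether a list moved relative to all other genes. It was run with a preset correlation between genes of 0.01 and again with a correlation estimated from the arrays, each adjusted over the 33 lists. The lists covered jasmonate (biosynthesis, JAZ repressors, signalling and turnover), specialised metabolism (terpene synthases, diterpenoid phytoalexin genes, the plastid isoprenoid or MEP pathway, phenylpropanoid genes), defence (protease inhibitors, pathogenesis-related proteins, receptor-like kinases) and transcription factors (WRKY, AP2/ERF, MYB, NAC, bHLH other than RERJ1, C2H2 zinc fingers). Others covered calcium signalling, heat shock and chaperones, glutathione and redox, ethylene biosynthesis, auxin response, gibberellin and brassinosteroid, abscisic acid, photosynthesis, cytosolic ribosomal proteins, cell wall loosening, cell wall deposition, the circadian clock, and autophagy and ubiquitin ligases. Markers of dividing cells and of other organs (root-type transporters, pollen and anther, seed storage) were included as signs of other cells. Members were found by locus and by words in the array's annotation. The list of pathogenesis-related proteins therefore shares members with the AP2/ERF list, the NAC list holds subunits of the nascent polypeptide-associated complex, and the photosynthesis list holds plastocyanin-like copper proteins. The AP2/ERF list likewise holds a gene annotated as an ethylene-responsive coactivator. The JAZ list holds Os02g0732400, which entered by a word of its annotation and not by locus, and which need not be a JAZ repressor.

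Genes were named by a rule. It took RERJ1, the 8 most raised and 6 most lowered described genes of each comparison among those past the threshold in the same direction on both replicates (of these the first 5 and 3 for wild type), and, where fewer than 3 passed in a direction, the 5 with the smallest p. It also took the 4 members with the largest change of each list that passed or held a changed gene, any member of the jasmonate biosynthesis, JAZ and terpene synthase lists, and the 15 wound-induced genes with the most negative change of the ratio.

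Replicate 1 and replicate 2 lay on separate slides, read on separate days, and each of the 2 slides held all 4 times. Each time took the same position on both slides. The replicate numbers pair the arrays: over 6 pairs of times, deviations of same-numbered arrays from their group means correlated with r from 0.347 to 0.658 across genes in Cy3, from 0.56 to 0.732 in Cy5 and from 0.233 to 0.629 for the ratio. The main model had no such block, and the model with the replicate as a block was an alternative. Other alternatives were the processed intensities, the deposited log ratios, median centring in place of loess, no Aquantile, no filter or a strict filter on dim probes, the mean of a gene's probes, a separate-channel model, no fold minimum, a plain rule of 2-fold in both replicates, and each array left out in turn.

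The code was tested on simulated data in which 50 genes per fold size were changed among 22629. For the wild-type change at 30 min, 17 of 50 genes changed 2-fold were recovered, 43 of 50 changed 3-fold and 48 of 50 changed 8-fold. For the ratio at 120 min, 24, 44 and 46 of 50 were recovered, and for the change of the ratio at 60 min 12, 43 and 45 of 50. These shares hold for the number of genes changed in the simulation. With fewer changed genes the adjusted p is stricter, so 0 genes passing would not exclude 3-fold changes. A shift given to the WRKY list was recovered and 0 of the other lists passed, with the preset correlation. The simulated noise was independent between probes, so this cannot show false list calls that arise from correlated genes.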

Results

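The leaves came from 2-week-old rice plantlets whose second leaf blade was pressed with a pin holder, per the labels, and were sampled at 0, 30, 60 and 120 min in wild type and in a line with a Tos17 insertion in RERJ1. Each of the 8 arrays held both genotypes of 1 time and replicate. Across arrays, 70.2% to 74.0% of the rice probes were well above background in Cy3 (wild type) and 74.0% to 77.1% in Cy5 (mutant). Replicates correlated across the genes tested, each read by its brightest probe past the filter, with r from 0.986 to 0.990 in Cy3 and from 0.987 to 0.991 in Cy5. For the log2 ratio of mutant over wild type r was 0.280 at 0 min, 0.483 at 30 min, 0.472 at 60 min and 0.570 at 120 min. Genes are not independent replicates.

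RERJ1 (Os04g0301500), a basic helix-loop-helix factor that responds to jasmonate, gave a lower signal in the mutant than in wild type on 8 of 8 arrays. In wild type its normalised log2 signal was 14.50 ± 1.35 (SD, n = 2) at 0 min, 16.14 ± 0.097 at 30 min, 14.75 ± 0.168 at 60 min and 10.24 ± 0.186 at 120 min. In the mutant it was 9.82 ± 1.27 at 0 min, 13.52 ± 0.036 at 30 min, 13.25 ± 0.045 at 60 min and 8.95 ± 0.115 at 120 min. Within the mutant the signal rose by 3.70 ± 0.508 (SE) log2 units at 30 min (adjusted p = 0.0038) and by 3.43 ± 0.508 at 60 min (adjusted p = 0.0018). Wild-type RERJ1 fell by 4.26 ± 0.539 at 120 min (adjusted p = 0.000887). Its change of 1.64 at 30 min missed the threshold (adjusted p = 0.0789) but passed with the replicate block (adjusted p = 0.0289). It was 2.60 without replicate 2 of 0 min and 0.68 without replicate 1 of 0 min. The wild-type change at 60 min (0.24, adjusted p = 0.736) turned on the same arrays, with 1.21 without replicate 2 of 0 min and -0.71 without replicate 1. So did the mutant's change at 120 min (-0.87, adjusted p = 0.192), with -1.79 and 0.015. These fits leave 1 array at 0 min, so only their sizes are given.

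The ratio of mutant over wild type for RERJ1 was -4.68 ± 0.741 at 0 min, -2.62 at 30 min, -1.49 at 60 min and -1.29 at 120 min, with adjusted p = 0.0895, 0.149, 0.298 and 0.371. The 0 min arrays set these p-values: their ratios were -2.83 and -6.53, with wild-type signals of 13.55 and 15.46. With the replicate block the 0 min ratio passed (adjusted p = 0.0364). The 0 min ratio was -6.53 without replicate 1 of 0 min and -2.83 without replicate 2. A fit with 1 array at 0 min leaves the disagreement of the 2 arrays out of the spread. Such fits therefore cannot check whether the ratio passes at any time. RERJ1 was read by 1 probe, a 60-mer well above background in both channels of every array. The position of that probe relative to the insertion is not given in the sources used here, so its signal does not check the loss of a full transcript.

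**Figure D1:**
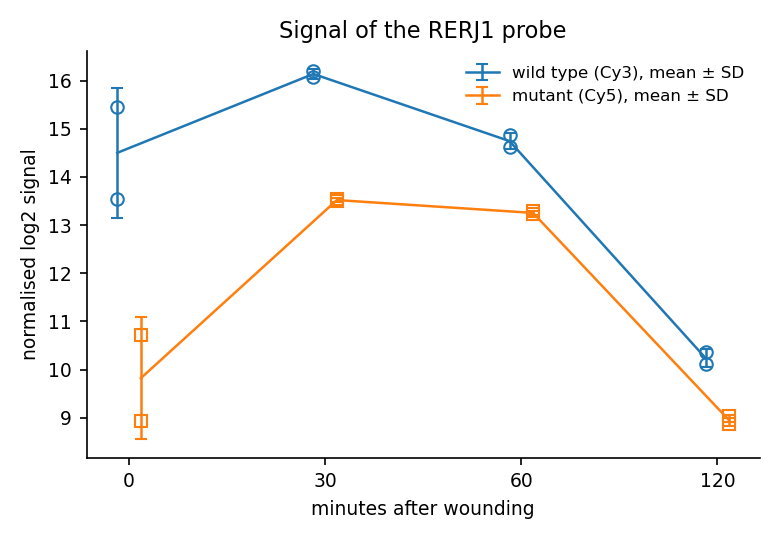
Normalised log2 signal of the RERJ1 probe (vertical axis) against minutes after wounding (horizontal axis, the 4 times evenly spaced) in wild type (Cy3, circles) and mutant (Cy5, squares), with single arrays as symbols, means as lines and the SD of 2 arrays as bars. The mutant lies below wild type at each time, with means of 9.82 against 14.50 at 0 min and 8.95 against 10.24 at 120 min.

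The first question was how wild-type leaves responded to wounding. At 30 min the most raised genes were the zinc finger genes ZPT2-14 (Os03g0820300), by 6.31 ± 0.298 log2 units (adjusted p = 6.42e-05), and ZPT2-13 (Os03g0820400), by 5.94 ± 0.384 (adjusted p = 0.000168). They were followed by cytochrome P450 genes (Os07g0635500, 5.89 ± 0.628; Os07g0419100, 5.69 ± 0.601) and a gene annotated as RAP2.6 (Os09g0457900, 5.53 ± 0.237), an AP2-domain factor. The most lowered were an auxin-induced gene (Os09g0545300, -3.69 ± 0.144), thioredoxin-like 1 (Os07g0684100, -3.62 ± 0.224) and a P450 gene (Os01g0543600, -3.27 ± 0.287). In all, 1445 genes rose and 542 fell of 22629 tested.

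Some jasmonate biosynthesis and JAZ genes rose at 30 min. Of 21 jasmonate biosynthesis genes, 6 rose and none fell (7 rose when adjusted over the list alone). Among them were both allene oxide synthases on the list, whose enzyme commits fatty acid hydroperoxides to jasmonate (Os03g0225900, 2.62 ± 0.672; Os03g0767000, 2.29 ± 0.195), and lipoxygenases such as Os04g0447100 (2.54 ± 0.178). The list passed upward with a median of 0.28 (camera adjusted p = 0.00536; adjusted p = 0.287 with an estimated correlation), but its median was -0.061 on replicate 1 and 1.09 on replicate 2. Of the 14 genes on the JAZ list, JAZ genes encoding the repressors of jasmonate signalling, 6 rose (6 adjusted over the list alone), led by Os03g0180800 (3.89 ± 0.213) and Os10g0391400 (3.06 ± 0.252). The list passed (adjusted p = 9.61e-05; adjusted p = 0.287 with an estimated correlation).

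Of 62 WRKY factors, regulators of defence genes, 23 rose at 30 min and none fell (24 adjusted over the list alone; median 0.57, adjusted p = 6.14e-10; adjusted p = 0.211 with an estimated correlation), with Os01g0821600 at 3.91, Os09g0417600 at 3.87 and WRKY24 (Os01g0826400) at 3.34. Calcium signalling genes rose in 27 of 143 cases and fell in none (27 adjusted over the list alone; adjusted p = 2.65e-06; adjusted p = 0.211 with an estimated correlation). Examples were an EF-hand gene (Os05g0380900, 4.97) and a calcium-dependent protein kinase (Os08g0540400, 2.98). Of 48 NAC genes, 9 rose and 1 fell both over all genes and adjusted over the list alone (adjusted p = 0.00384; adjusted p = 0.211 with an estimated correlation), with Os01g0862800 at 3.84. Among 73 AP2/ERF factors, 19 rose and 3 fell by either adjustment (adjusted p = 0.00809; adjusted p = 0.282 with an estimated correlation). Among 66 receptor-like kinases 8 rose and 2 fell by either adjustment (adjusted p = 0.0184; adjusted p = 0.293 with an estimated correlation). The receptor-like kinase list no longer passed without Aquantile (adjusted p = 0.0608) or without replicate 1 of 30 min (adjusted p = 0.0601).

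Of 48 markers of dividing cells, listed as a sign of meristem or leaf base in the sample, 17 fell and none rose at 30 min by either adjustment (median -0.75, adjusted p = 7.2e-08; adjusted p = 0.444 with an estimated correlation). Examples among the histones were H1 (Os03g0799000, -2.15), H4 (Os09g0553100, -1.91) and H2B.2 (Os05g0574300, -1.88). The cytosolic ribosomal proteins shifted slightly lower (median of 149 genes -0.29, adjusted p = 8.42e-08; adjusted p = 0.444 with an estimated correlation) with 2 fallen members, both annotated as 40S protein S9 (Os07g0628300, -1.67; Os03g0379500, -1.21). The median change of all genes was -0.13 at 30 and at 60 min and -0.01 at 120 min, and camera sets each list against the other genes.

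By 60 min, 2578 genes had risen and 2261 had fallen in wild type. A UDP-glucosyltransferase family gene (Os05g0527000) rose by 7.28 ± 0.184 log2 units (adjusted p = 1.1e-05) and a GDSL lipase gene (Os10g0393800) by 6.74 ± 0.301. Glutathione S-transferase GST 19 (Os03g0785900) rose by 6.70 ± 0.318, an isopenicillin N synthase family gene (Os04g0581100) by 6.59 ± 0.258 and the P450 gene Os07g0419100 by 6.56 ± 0.601. The most lowered were another UDP-glucosyltransferase family gene (Os05g0177500, -5.20 ± 0.16), a zinc finger gene (Os02g0148000, -5.10 ± 0.246) and a P450 gene (Os11g0487600, -5.01 ± 0.201). At the same adjusted p but with no fold minimum, 4526 genes passed at 30 min, 10794 at 60 min and 11189 at 120 min.

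Jasmonate biosynthesis had 9 raised and 1 lowered member at 60 min by either adjustment (median 1.11, adjusted p = 0.00249; adjusted p = 0.555 with an estimated correlation). The raised ones included lipoxygenase Os03g0700700 (3.81 ± 0.124), allene oxide synthase Os03g0767000 (3.44 ± 0.195), allene oxide cyclase Os03g0438100 (1.78 ± 0.241) and the 12-oxophytodienoate reductase Os08g0459600 (1.33). JAZ genes had 6 raised members by either adjustment (median 0.85, adjusted p = 0.00506; adjusted p = 0.607 with an estimated correlation), with Os03g0180800 at 3.91 and Os03g0180900 at 3.36. In the phenylpropanoid list, the pathway to lignin and flavonoids, 23 of 60 genes rose and none fell (24 adjusted over the list alone; median 0.60, adjusted p = 4.3e-05; adjusted p = 0.664 with an estimated correlation). A pair of cinnamate 4-hydroxylase genes rose (Os02g0467000, 6.49; Os02g0467600, 4.79), as did cinnamyl alcohol dehydrogenase CAD1 (Os04g0229100, 3.83). That list had passed at 30 min too, with 13 raised members (15 adjusted over the list alone). Its median there was -0.004 and its mean 0.465, with an upward test (adjusted p = 0.00809; adjusted p = 0.69 with an estimated correlation). It did not pass without replicate 2 of 0 min (adjusted p = 0.387).

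AP2/ERF factors rose in 27 of 73 cases at 60 min and fell in 4 by either adjustment (adjusted p = 3.48e-05; adjusted p = 0.243 with an estimated correlation). A gene annotated as an ethylene-responsive coactivator (Os06g0592500), which entered this list by those words, stood at 5.43. Among 82 genes annotated as pathogenesis-related proteins, 19 rose and 7 fell by either adjustment (adjusted p = 0.013; adjusted p = 0.764 with an estimated correlation), for example thaumatin-like protein Os03g0244200 (5.35) and chitinase A (Os02g0605900, 4.28). WRKY factors had 20 raised and 5 lowered members by either adjustment (adjusted p = 0.0158; adjusted p = 0.555 with an estimated correlation), with WRKY34 (Os05g0583000) at 4.50 and WRKY60 (Os03g0657400) at 4.09. Receptor-like kinases had 12 raised and 6 lowered members (13 and 6 adjusted over the list alone; adjusted p = 0.0403; adjusted p = 0.555 with an estimated correlation). The pathogenesis-related list ended without replicate 1 of 60 min (adjusted p = 0.0592) or replicate 2 of 0 min (adjusted p = 0.11). The receptor-like kinase list ended without replicate 1 of 0 min (adjusted p = 0.0567), without replicate 1 of 60 min (adjusted p = 0.0803), with the strict filter (adjusted p = 0.12) and without Aquantile (adjusted p = 0.137).

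At 120 min, 2356 genes were raised and 2809 lowered. A dioxygenase annotated as RAMOSUS1 (Os01g0566500), a name used in pea for a carotenoid-cleaving enzyme of strigolactone synthesis, rose by 8.10 ± 0.298 log2 units and a flavin-containing monooxygenase gene (Os04g0223500) by 8.07 ± 0.31 (adjusted p = 2.75e-05 for both). The GDSL lipase gene Os10g0393800 stood at 6.99 ± 0.301, the coactivator Os06g0592500 at 6.75 ± 0.319 and cinnamate 4-hydroxylase Os02g0467000 at 6.58 ± 0.35. The most lowered were a Myb gene (Os05g0579600, -5.94 ± 0.273), the UDP-glucosyltransferase family gene Os05g0177500 (-5.86 ± 0.16) and a CBF-like gene (Os09g0522000, -4.88 ± 0.281), CBF factors being regulators of cold responses.

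Ribosomal protein genes rose together at 120 min, 46 of 149 and none fallen by either adjustment (median 0.88, adjusted p = 1.19e-23; adjusted p = 0.75 with an estimated correlation), for example 40S protein S2 (Os07g0207400, 2.09) and 60S protein L9 (Os02g0103700, 2.06). Of 131 heat shock and chaperone genes, 37 rose and 9 fell by either adjustment (adjusted p = 0.00856; adjusted p = 0.75 with an estimated correlation), led by small heat shock proteins (Os03g0266900, 6.01; Os01g0184100, 5.93) and heat shock factor RHSF2 (Os08g0546800, 5.30). Phenylpropanoid genes had 24 raised members and 1 lowered by either adjustment (median 0.78, adjusted p = 5.21e-05; adjusted p = 0.75 with an estimated correlation), with a phenylalanine ammonia-lyase (Os05g0427400), the entry enzyme of the pathway, at 3.27. Of 77 photosynthesis genes, 24 fell and 4 rose by either adjustment (median -0.59, adjusted p = 0.00856; adjusted p = 0.866 with an estimated correlation). The fallen ones included the photosystem II 10 kDa polypeptide (Os07g0147500, -3.11) and a chlorophyll a/b-binding protein (Os09g0439500, -3.07), and 2 of the raised ones were plastocyanin-like copper proteins (Os02g0758800, 3.74; Os03g0709300, 3.29). Jasmonate biosynthesis had 8 raised and 1 lowered member by either adjustment (median 1.42) and missed the list threshold (adjusted p = 0.0501; adjusted p = 0.75 with an estimated correlation). It passed with no filter on dim probes (adjusted p = 0.018), with the mean of a gene's probes (adjusted p = 0.0369) and without Aquantile (adjusted p = 0.032). The JAZ list passed at 120 min without replicate 2 of 0 min (adjusted p = 0.0105).

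**Figure D2:**
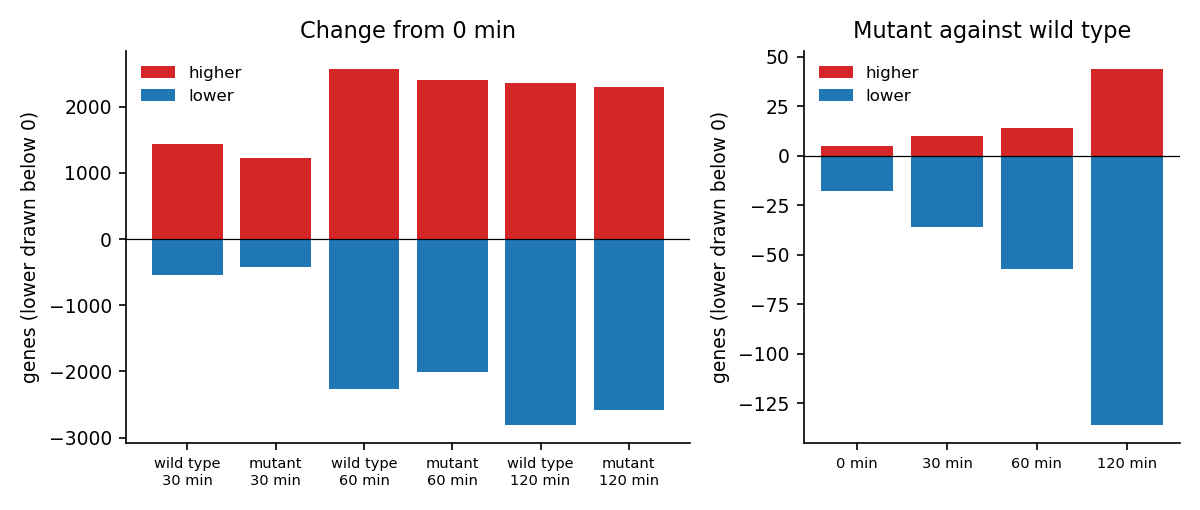
Number of genes past the threshold (vertical axes; lower genes drawn below 0) for the change from 0 min in each genotype (left) and for mutant against wild type at each time (right; another vertical scale). In wild type 1445 genes were higher and 542 lower at 30 min, and in the mutant against wild type at 120 min 44 were higher and 136 lower.

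The remaining lists passed at no time in wild type and are given as genes raised and lowered at 30, 60 and 120 min. Within jasmonate signalling and turnover (5 genes) a P450 gene (Os12g0150200) rose at 30 min (2.92) and 60 min (2.65), and a receptor gene annotated as COI1 (Os05g0449500) fell at 60 min (-1.36) and 120 min (-1.40). Terpene synthases (18 genes) had 0 and 0, 2 and 1, then 3 and 1; Os02g0121700 rose at 60 min (4.22) and 120 min (5.23), Os04g0345400 likewise (3.59 and 3.14), and Os11g0474800 rose at 120 min by at least 2.73-fold. The diterpenoid phytoalexin genes (15) had 0 and 0, 1 and 1, then 2 and 0, and the MEP pathway (15) 0 and 0, 2 and 0, then 1 and 2, where deoxyxylulose phosphate synthase Os07g0190000 rose at 60 min (2.48) and 120 min (2.79). Protease inhibitors (40) had 2 and 0, 5 and 1, then 7 and 1. MYB factors (136) had 15 and 16, 28 and 20, then 17 and 28, bHLH factors other than RERJ1 (79) 9 and 3, 14 and 12, then 9 and 12, and C2H2 zinc fingers (58) 11 and 3, 11 and 6, then 5 and 3. Glutathione and redox genes (199) had 25 and 2, 33 and 18, then 37 and 39.

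Among hormone lists, ethylene biosynthesis (12) had 0 and 0, then 2 and 2 at both later times, and auxin response (63) had 6 and 4, 12 and 10, then 9 and 16. Gibberellin and brassinosteroid genes (20) had 4 and 1, 2 and 1, then 1 and 5, and abscisic acid (72) 14 and 4, 14 and 15, then 4 and 14. Cell wall loosening genes (24) had 5 and 2, 4 and 7, then 3 and 4, and cell wall deposition genes (32) 4 and 1, 5 and 1, then 4 and 2. The clock list (8) had 0 and 1, 1 and 2, then 0 and 3, with a Myb gene (Os08g0157600) at -2.20 at 120 min. Autophagy and ubiquitin ligase genes (22) had 1 and 2, 2 and 4, then 1 and 0. Of the markers of other organs, root-type transporters (17) had 2 and 0, 2 and 3, then 1 and 4, and pollen and anther genes (11) 0 raised and 1, 1 and 2 lowered. Seed storage genes (21) had 4 and 0, 6 and 0, then 4 and 1. Glutelin family genes (Os03g0188500, 4.20; Os12g0283400, 3.50) and late embryogenesis abundant proteins were among those raised at 30 min. With the replicate block the seed storage list passed at 60 min (adjusted p = 0.0394 against 0.113; adjusted p = 0.669 with an estimated correlation), and a few of these lists did without single arrays, such as cell wall deposition at 30 min without replicate 1 of 0 min (adjusted p = 0.00631). Adjusted over the list alone, these counts changed by at most 2 genes in any list.

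The mutant's own response was the second comparison. JAZ genes rose in 8, 9 and 8 of 14 cases at 30, 60 and 120 min, with medians of 1.40, 2.16 and 1.13; Os10g0391400 rose by 5.85 ± 0.357 at 30 min. The list passed each time (adjusted p = 7.11e-07, 0.000102 and 0.00496; adjusted p = 0.316, 0.575 and 0.661 with an estimated correlation). In jasmonate biosynthesis 6 and 9 of 21 genes rose at 30 and 60 min (adjusted p = 0.00156 and 0.00268; adjusted p = 0.316 and 0.575 with an estimated correlation). Over all genes, 1219 rose and 426 fell at 30 min, 2400 rose and 2004 fell at 60 min, and 2305 rose and 2576 fell at 120 min.

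WRKY factors rose in 14 of 62 cases at 30 min and markers of dividing cells fell in 12 of 48, while at 120 min 48 of 149 ribosomal protein genes rose. These lists passed (adjusted p = 3.16e-08, 1.74e-08 and 9.68e-23; adjusted p = 0.316, 0.316 and 0.538 with an estimated correlation). Photosynthesis genes fell in 14 and rose in 6 of 77 cases at 120 min (adjusted p = 0.0116; adjusted p = 0.661 with an estimated correlation), but the list did not pass without replicate 1 of 120 min (adjusted p = 0.0795). Phenylpropanoid genes rose in 14, 23 and 25 of 60 cases (adjusted p = 0.000651, 8.41e-05 and 1.9e-05; adjusted p = 0.316, 0.286 and 0.441 with an estimated correlation). Adjusted over the list alone, these counts were the same except for 13 fallen markers of dividing cells. With the processed intensities 2577 genes passed in the mutant at 30 min instead of 1645.

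The mutant's AP2/ERF factors also passed, at 30 min (adjusted p = 0.0039) and 60 min (adjusted p = 1.94e-05), as did calcium signalling at 30 min (adjusted p = 5.31e-05) and heat shock genes at 120 min (adjusted p = 0.00768). With an estimated correlation these had adjusted p = 0.509, 0.575, 0.075 and 0.538. Ribosomal protein genes were lower at 30 min (adjusted p = 1.12e-10; adjusted p = 0.509 with an estimated correlation). NAC factors (adjusted p = 0.0189) and cell wall deposition genes (adjusted p = 0.00662) passed upward at 30 min, with adjusted p = 0.438 and 0.316 with an estimated correlation. The NAC list did not pass without replicate 2 of 0 min (adjusted p = 0.0669), nor cell wall deposition with the strict filter (adjusted p = 0.106). WRKY factors passed at 60 min (adjusted p = 0.0277; adjusted p = 0.64 with an estimated correlation), but not without replicate 1 of 60 min (adjusted p = 0.0528) or replicate 2 of 0 min (adjusted p = 0.177). Pathogenesis-related proteins passed upward at 30 min (adjusted p = 0.0459, with a median of -0.013) and 60 min (adjusted p = 0.0231), with adjusted p = 0.316 and 0.286 with an estimated correlation. The 30 min call was lost without replicate 1 of 0, 60 or 120 min (adjusted p = 0.148, 0.0513 and 0.0527) or replicate 2 of 30 or 60 min (adjusted p = 0.105 and 0.0512), and with median centring, no filter or no Aquantile (adjusted p = 0.0812, 0.0557 and 0.0839). The 60 min call was lost without Aquantile (adjusted p = 0.0716), as was the WRKY call (adjusted p = 0.124) and, at 30 min, cell wall deposition (adjusted p = 0.0539).

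Seed storage genes, markers of another organ, passed in the mutant at 60 min with 6 raised and 1 lowered of 21 (median 0.51, adjusted p = 0.0455; adjusted p = 0.64 with an estimated correlation). Among them were the glutelin family genes Os03g0188500 (2.89 ± 0.275) and Os12g0283400 (2.40 ± 0.564) that also rose in wild type. The list did not pass with the processed intensities (adjusted p = 0.0767), with median centring (adjusted p = 0.0546) or without Aquantile (adjusted p = 0.132). Nor did it without replicate 1 of 0 or 60 min (adjusted p = 0.0565 and 0.0584) or replicate 2 of 0 or 30 min (adjusted p = 0.0708 and 0.0502). Its ratio did not change from 0 to 60 min by the test (adjusted p = 0.961).

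**Figure D3:**
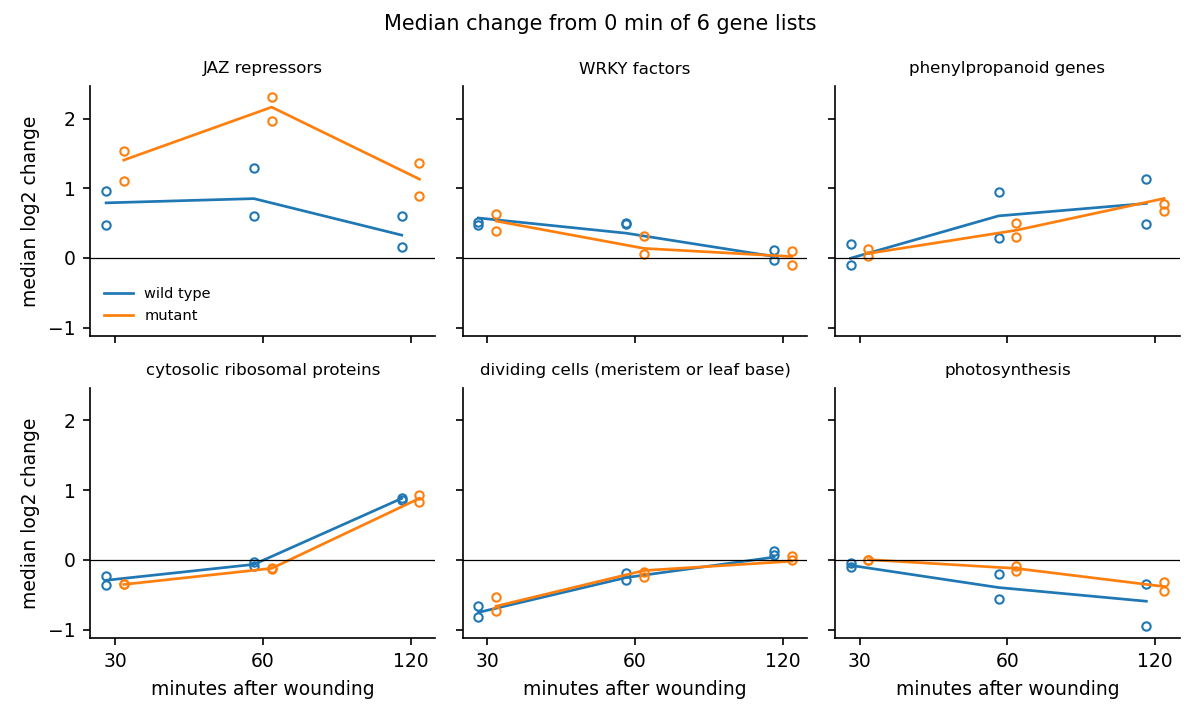
Median log2 change from 0 min (vertical axes) of 6 gene lists at 30, 60 and 120 min after wounding (horizontal axes) in wild type (blue) and mutant (orange); lines join the estimates from both replicates and open circles are the medians of single replicates. Ribosomal protein genes reach 0.88 at 120 min in both genotypes, and JAZ genes reach 0.85 in wild type and 2.16 in the mutant at 60 min.

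The third comparison set the mutant directly against wild type at each time. At 0 min, JAZ genes were lower in the mutant. Of 14, 1 passed over all genes (Os09g0439200, -2.11 ± 0.202, adjusted p = 0.0272) and 7 adjusted over the list alone. The list median was -1.18 (adjusted p = 1.89e-08; adjusted p = 0.616 with an estimated correlation), with medians of -0.61 and -1.52 on the replicates. Jasmonate biosynthesis genes were lower as a list (median of 21 genes -0.30, adjusted p = 0.00985; adjusted p = 0.801 with an estimated correlation). They did not pass with the replicate block (adjusted p = 0.0522) or without replicate 2 of 0 min (adjusted p = 0.0535). Phenylpropanoid genes (median -0.18, adjusted p = 0.000157), protease inhibitors (median -0.03, adjusted p = 0.0434) and terpene synthases (median -0.24, adjusted p = 0.0434) were also lower, with adjusted p = 0.801, 0.801 and 0.761 with an estimated correlation. None of these 3 lists passed without replicate 1 of 0 min (adjusted p = 0.29, 0.871 and 0.477), and the terpene synthases did not with the replicate block (adjusted p = 0.0539) or without either array of 60 min (adjusted p = 0.0525). Protease inhibitors did not with the mean of a gene's probes (adjusted p = 0.0512) or without replicate 1 or 2 of 120 min (adjusted p = 0.0542 and 0.0539). Within them 1, 0 and 0 genes were lower over all genes, and 3, 2 and 1 adjusted over the list alone.

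Among genes past the threshold with a description, the largest ratios at 0 min were those of a ribonuclease P-related gene (Os05g0270500), lower by -5.22 ± 0.138 log2 units (adjusted p = 0.000209), and a phosphatidate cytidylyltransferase gene (Os11g0105800, -3.52 ± 0.214). Lower too were 3 neighbouring protein kinase genes (Os01g0699500, -2.99 ± 0.273; Os01g0699600, -2.53 ± 0.266; Os01g0699400, -2.12 ± 0.196). The nicotianamine aminotransferase gene OsNAAT1, needed to make iron-binding phytosiderophores, was at -2.31 ± 0.111. Among raised genes past the threshold a paired amphipathic helix gene (Os06g0494000) stood at 2.59 ± 0.126 and a Mov34 family gene (Os12g0622900) at 1.59 ± 0.087. Of 22629 genes 5 were higher and 18 lower at 0 min. With the processed intensities, and with the deposited log ratios, 8 were higher and 13 lower, with median centring 14 and 33, and with the replicate block 47 and 98. Without replicate 1 of 0 min 97 genes passed, and 9 without replicate 1 of 60 min.

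At 30 min, jasmonate genes were again lower in the mutant, with lipoxygenase Os04g0456700 at -1.02 ± 0.113 (adjusted p = 0.0319) as the 1 gene past the threshold in jasmonate biosynthesis. That list (median -0.27, adjusted p = 0.00389) and the JAZ genes (median -0.48, adjusted p = 0.00104; 0 over all genes and 4 adjusted over the list alone) were lower. So were the phenylpropanoid genes (median -0.11, adjusted p = 0.0163; cinnamoyl-CoA reductase Os08g0277200 at -1.69 ± 0.14), each of these lists with adjusted p = 0.778 with an estimated correlation. With median centring the jasmonate biosynthesis and phenylpropanoid lists no longer passed (adjusted p = 0.194 and 0.058), as without replicate 2 (adjusted p = 0.0546) and replicate 1 (adjusted p = 0.0869) of 30 min. Protease inhibitors (median -0.12, adjusted p = 0.0591) passed with the replicate block (median -0.12, adjusted p = 0.0224; adjusted p = 0.663 with an estimated correlation). They also did with median centring (median -0.39, adjusted p = 0.00116), the processed intensities (median -0.26, adjusted p = 0.0477) and the deposited log ratios (median -0.225, adjusted p = 0.0499), and without either array of 0 min (adjusted p = 0.0258) or replicate 1 or 2 of 60 min (adjusted p = 0.0437 and 0.0436). Genes higher in the mutant included a reverse transcriptase fragment (Os07g0641500, at least 4.35-fold), a phytosulfokine precursor gene (Os11g0149400, 1.11 ± 0.075), phytosulfokine being a growth-promoting peptide. A metallophosphoesterase gene (Os11g0261900) was lower (-1.64 ± 0.218).

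Over all genes 10 were higher and 36 lower at 30 min, against 11 and 10 with the processed intensities and with the deposited log ratios, 151 and 90 with median centring and 46 and 109 with the replicate block. Without replicate 1 or without replicate 2 of 30 min 1 gene passed, and 10 without either array of 120 min. The 1 gene was the ribonuclease P-related gene Os05g0270500, lower by -5.35 log2 units with all arrays.

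At 60 min, 14 genes were higher and 57 lower in the mutant. A phospholipase D gene (Os06g0604200), whose enzyme cuts membrane lipids, was lower by -3.34 ± 0.323 log2 units (adjusted p = 0.0214), and a prolyl endopeptidase gene (Os04g0561500) by -2.46 ± 0.305. Lower too were an ERF gene (Os11g0129700, -2.21 ± 0.3) and a WD40 gene (Os04g0481600, -2.14 ± 0.156). A TPR-domain gene (Os10g0576600) was higher by 1.81 ± 0.076 (adjusted p = 0.00199), and a Bowman-Birk trypsin inhibitor (Os03g0823400) and a dehydration-responsive element binding factor (Os04g0549700) were lower (-1.87 and -1.43). In jasmonate biosynthesis lipoxygenase Os04g0456700 (-1.40) and allene oxide cyclase Os03g0438100 (-1.02) were lower (3 adjusted over the list alone; list median -0.16, adjusted p = 0.00378). The phenylpropanoid list (median -0.21, adjusted p = 0.00378) was lower too, and photosynthesis genes were higher (median 0.31, adjusted p = 0.00378), all 3 lists with adjusted p = 0.862 with an estimated correlation. The JAZ list was lower with loess (median -0.23, adjusted p = 0.0372; adjusted p = 0.862 with an estimated correlation; 0 over all genes and 3 adjusted over the list alone) but its median turned to 0.114 with median centring (adjusted p = 0.252). The markers of dividing cells were lower with loess (median -0.18, adjusted p = 0.00241; adjusted p = 0.862 with an estimated correlation), with a median of 0.087 with median centring (adjusted p = 0.892). With median centring the jasmonate biosynthesis and phenylpropanoid lists did not pass (adjusted p = 0.273 and 0.138).

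Without replicate 2 of 60 min the jasmonate biosynthesis, JAZ, phenylpropanoid and photosynthesis lists did not pass (adjusted p = 0.156, 0.158, 0.177 and 0.43). Without replicate 1 the markers of dividing cells did not (adjusted p = 0.0968), and with the replicate block the JAZ list did not (adjusted p = 0.0909). Other counts of genes higher and lower were 20 and 29 with the processed intensities and with the deposited log ratios, 245 and 109 with median centring and 54 and 133 with the replicate block. Without replicate 1 or replicate 2 of 60 min 1 gene passed, Os05g0270500, and without either array of 30 min 27 did.

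At 120 min 44 genes were higher and 136 lower in the mutant. A Bowman-Birk proteinase inhibitor (Os01g0127600), a class of inhibitors that act against insect digestive enzymes, was lower by -6.35 ± 0.903 log2 units (adjusted p = 0.0284), and the prolyl endopeptidase Os04g0561500 by -3.74 ± 0.305. A KpsF family gene (Os02g0158300) was at -3.24 ± 0.28 and an aspartic peptidase gene (Os04g0535200) at -2.79 ± 0.276. Higher were the photosystem II 10 kDa polypeptide (Os07g0147500, 3.22 ± 0.335, adjusted p = 0.0147), another aspartic peptidase gene (Os05g0384300, 2.17 ± 0.265) and a peroxidase (Os10g0109600, 2.13 ± 0.233). So were RAV2 (Os02g0764100, 1.89 ± 0.322) and protochlorophyllide reductase A (Os04g0678700, 1.87 ± 0.329), an enzyme of chlorophyll synthesis.

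Jasmonate biosynthesis genes were lower at 120 min (median -0.48, adjusted p = 3.6e-05; adjusted p = 0.684 with an estimated correlation), with lipoxygenases Os02g0753300 (-1.45) and Os04g0456700 (-1.32) past the threshold and 3 genes adjusted over the list alone. The JAZ list was lower with loess (median -0.38, adjusted p = 0.00618; adjusted p = 0.684 with an estimated correlation), with a median of 0.015 with median centring (adjusted p = 0.0917). In it 1 gene was lower over all genes, Os09g0439200 at -1.24, and 3 adjusted over the list alone. Terpene synthases were lower (median -0.29, adjusted p = 0.0109; adjusted p = 0.684 with an estimated correlation), with Os03g0348200 at -1.35. The markers of dividing cells were lower with loess (median -0.13, adjusted p = 0.000582; adjusted p = 0.684 with an estimated correlation) and did not pass with median centring (median 0.13, adjusted p = 0.965). Diterpenoid phytoalexin genes (median -0.36, adjusted p = 0.00618) and cell wall deposition genes (median -0.12, adjusted p = 0.0105) were lower, with adjusted p = 0.768 with an estimated correlation. Examples of the latter were a fasciclin-domain gene (Os07g0160600, -1.50) and cellulose synthase-4 (Os07g0208500, -1.07). Photosynthesis genes were higher (median 0.30, adjusted p = 0.0187; adjusted p = 0.926 with an estimated correlation), but not without replicate 2 of 120 min (median -0.024, adjusted p = 0.825) or with the processed intensities (adjusted p = 0.0506). Without replicate 2 of 120 min the JAZ and diterpenoid lists did not (adjusted p = 0.0538 and 0.0582), nor without replicate 1 the cell wall deposition list (adjusted p = 0.103).

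Counts at 120 min were 55 and 90 with the processed intensities, 57 and 90 with the deposited log ratios, 232 and 180 with median centring and 94 and 205 with the replicate block. Without replicate 1 of 120 min 17 genes passed, and without replicate 2 of 120 min 3 did (Os05g0270500, Os04g0535200 and the Myb gene Os08g0128000, chosen after its values were seen). The 149 ribosomal protein genes were slightly lower at each time with loess (medians -0.07, -0.12, -0.13 and -0.07) and higher with median centring (0.23, 0.30, 0.34 and 0.42). With loess they had adjusted p = 0.000157, 1.06e-08, 1.64e-07 and 0.00555, and adjusted p = 0.98, 0.778, 0.862 and 0.926 with an estimated correlation. The 120 min shift did not pass without replicate 2 of 120 min (median 0.018, adjusted p = 0.704), nor the 30 min shift without replicate 2 of 30 min (adjusted p = 0.131). The markers of dividing cells were lower at 0 min too (median -0.15, adjusted p = 0.000157; adjusted p = 0.801 with an estimated correlation) with loess but not with median centring (median 0.041, adjusted p = 0.48) or without replicate 1 of 0 min (median -0.10, adjusted p = 0.098).

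**Figure D4:**
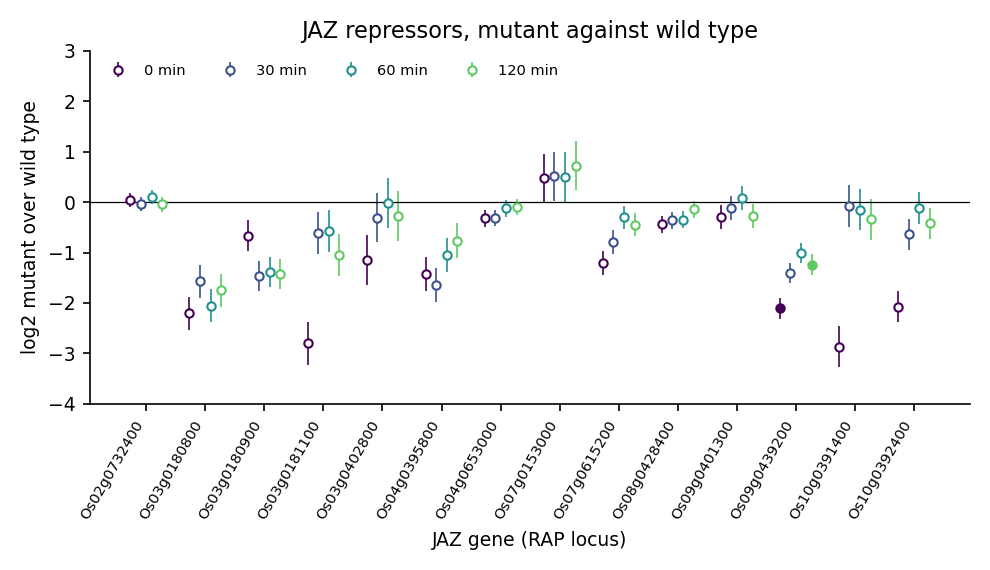
Log2 ratio of mutant over wild type (vertical axis) for each of the 14 genes on the JAZ list (horizontal axis, by locus) at 0, 30, 60 and 120 min, with standard errors as bars and filled points where a gene passed the threshold over all genes. Os10g0391400 lies at -2.86 at 0 min and at -0.16 at 60 min, and Os09g0439200 was past the threshold at 0 min (-2.11) and 120 min (-1.24).

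Whether wounding itself acted differently in the mutant was tested as the change of the ratio from 0 min. In this test by limma 0 genes passed at any time, and 722, 1475 and 1403 genes had an unadjusted p under 0.05 at 30, 60 and 120 min against 1131 expected by chance. The TPR-domain gene Os10g0576600 came nearest at 60 min (1.42 ± 0.108, adjusted p = 0.164), followed by a dynein light chain gene (Os01g0760000, 1.54 ± 0.191) and, with a negative change, the bHLH gene Os01g0159800 (-0.90 ± 0.112) and the WD40 gene Os04g0481600 (-1.76 ± 0.221), each of the 3 with adjusted p = 0.379. At 30 min a CBF-like gene (Os09g0522000) stood at 1.84 ± 0.21 and an AAA ATPase gene (Os03g0802500) at -1.48 ± 0.158 (adjusted p = 0.543 for both), and at 120 min a short-chain dehydrogenase gene (Os07g0592100) at -1.80 ± 0.246 (adjusted p = 0.394). The moderated F test over the 4 times passed 0 genes, with 1406 at an unadjusted p under 0.05 and a smallest adjusted p of 0.207. Without replicate 1 of 0 min 10, 6 and 6 genes passed at 30, 60 and 120 min and 8 in the F test, and without replicate 2 of 120 min 1 gene did at 120 min (the Myb gene Os08g0128000, chosen after its values were seen).

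The last comparison asked which wound-induced genes depended on RERJ1. Since 0 genes passed the change of the ratio in limma, 0 met the definition chosen in advance; without replicate 2 of 120 min 1 did. At an unadjusted p under 0.05 and a change of the ratio of -1 or less, 75 wound-induced genes were counted. The median was 9 (range 6 to 16) in 20 simulations that removed any difference in wound response but kept each gene's mean ratio. Their noise was drawn gene by gene, without errors shared among the genes of an array. In the opposite direction, with a change of 1 or more, 48 were counted against a simulated median of 6 (range 1 to 14). The alpha-expansin OsEXPA2 (Os01g0823100), a protein that loosens cell walls, changed by 3.17 log2 units in wild type and by 0.61 in the mutant at 120 min (difference -2.57 ± 0.751, unadjusted p = 0.0129). For CAD1 (Os04g0229100) at 60 min the values were 3.83 and 1.32 (difference -2.51 ± 0.868, unadjusted p = 0.0256). For phospholipase D Os06g0604200 at 60 min they were 3.64 and 1.42 (-2.22 ± 0.456) and for a translation initiation factor SUI1 gene (Os04g0627900) at 60 min 6.44 and 4.07 (-2.37 ± 0.388). The ratio of mutant over wild type at 0 min was already 1.75 for the SUI1 gene and -1.12 for phospholipase D. The ERF gene Os11g0129700 at 60 min had 2.41 and 0.41, and arginine decarboxylase (Os04g0107600), an enzyme of polyamine synthesis, at 120 min 1.75 and -0.19 (-1.95 ± 0.306). A pair of benzoyl transferase genes (Os10g0503300, Os06g0710700) differed by -1.98 and -1.97 at 60 min.

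The count of 75 became 185 with the processed intensities, 141 with the deposited log ratios, 43 with the strict filter, and 40 with median centring. It became 163 without replicate 1 of 0 min, 156 without replicate 2 of 0 min and 118 without replicate 2 of 30 min. By a definition added after the data were seen, induced in wild type and past the threshold below wild type at the same time, 81 genes counted. The same simulations, which kept each gene's mean ratio, gave a median of 56 (46 to 67). Examples are phospholipase D (Os06g0604200, ratio -3.34 at 60 min and -1.12 at 0 min) and the aspartic peptidase Os04g0535200 (-2.79 at 120 min and -0.47 at 0 min). The added definition does not ask for a lower response in the mutant. Most of the 81 genes rose less in the mutant, which the definition itself favours, since the wild-type signal at that time enters both its criteria. The JAZ gene Os09g0439200, however, rose by 3.21 in wild type and 4.08 in the mutant at 120 min. Its ratio was already -2.11 at 0 min. With the replicate block 137 genes counted, with the processed intensities 37, with the deposited log ratios 26, and without replicate 1 or 2 of 120 min 17 or 12.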

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

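Of the tests in this part, the one on errors in the wild-type signal was written before its result was seen, and those on early wound genes, constant dye effects, other probes, neighbouring genes and the opposite direction only after.

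Several gene lists drew attention because the ratio of mutant over wild type differed between a later time and 0 min, by the preset camera test of the difference. At 30 min the median changes were 0.293 for JAZ repressors (adjusted p = 0.0112), 0.096 for markers of dividing cells (0.0035), -0.043 for WRKY factors (0.0461), -0.049 for calcium signalling (0.0289), -0.055 for ribosomal proteins (0.0035) and -0.081 for receptor-like kinases (0.0461). At 60 min they were 0.372 for JAZ repressors (adjusted p = 0.00213) and 0.3 for photosynthesis (0.00118). At 120 min they were 0.556 for JAZ repressors (adjusted p = 0.00456), 0.275 for photosynthesis (0.00456), 0.087 for glutathione and redox (0.00456), -0.087 for jasmonate biosynthesis (0.0219) and -0.195 for diterpenoid phytoalexin genes (0.0469). With an estimated correlation none of these passed, the lowest adjusted p being 0.696. The JAZ change did not pass at 30 min with median centring (adjusted p = 0.0804), without replicate 2 of 0 min (median -0.012, adjusted p = 0.172) or without replicate 2 of 30 min (adjusted p = 0.0913), at 60 min without replicate 1 of 60 min (adjusted p = 0.17), or at 120 min without replicate 1 of 120 min (adjusted p = 0.11).

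The other list calls were lost as well. At 30 min the WRKY call was lost with the processed intensities, median centring, the strict filter and the deposited log ratios (adjusted p = 0.186, 0.347, 0.2 and 0.0863). It was also lost without replicate 1 of 0, 30 or 120 min (0.568, 0.0662 and 0.0514) and without replicate 2 of 30 or 120 min (0.382 and 0.0514). Receptor-like kinases lost theirs under the same settings (0.246, 0.0909, 0.2 and 0.307), without replicate 1 of 0, 30 or 60 min (0.177, 0.823 and 0.0859) and without replicate 2 of 0 or 60 min (0.159 and 0.086). Calcium signalling lost its call with median centring and the strict filter (0.694 and 0.13), without replicate 1 of 0 or 30 min (0.0716 and 0.185) and without replicate 2 of 0 min (0.156). Markers of dividing cells lost it with median centring (0.145), without replicate 1 of 0 min (0.455) and without replicate 2 of 30 min (0.646). Ribosomal proteins lost it with median centring (0.4) and without replicate 2 of 0 or 30 min (0.076 and 0.688). Photosynthesis lost the 60 min call without replicate 2 of 60 min (0.452), and the 120 min call with median centring (0.0632), without replicate 1 of 0 min (0.0637) and without replicate 2 of 120 min (0.676). At 120 min jasmonate biosynthesis lost its call with median centring and the strict filter (0.25 and 0.0903; medians -0.021 and -0.012), without replicate 1 of 0 min (0.237; median -0.357) and without replicate 2 of 120 min (0.664; median 0.025). Diterpenoid genes lost theirs with the processed intensities, median centring, the strict filter, the replicate block and the deposited log ratios (0.507, 0.0923, 0.351, 0.0664 and 0.518) and without replicate 2 of 0 or 120 min (0.64 and 0.404). Glutathione and redox genes lost it without replicate 1 of 0 min (0.265). Some of these medians turned sign: WRKY factors without replicate 1 of 0 min (0.023), receptor-like kinases without replicate 1 of 30 min (0.03), calcium signalling and ribosomal proteins with median centring (0.017 and 0.055), ribosomal proteins without replicate 2 of 30 min (0.017) and photosynthesis at 120 min without replicate 2 of 120 min (-0.075).

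JAZ repressors were lower in the mutant at 0 min as a list by the preset camera test, but not with an estimated correlation. There, 1 of 14 members passed over all genes. A constant dye effect of the JAZ probes would leave the ratio unchanged over time, but 4 members had a ratio change past the test adjusted over the list alone at 60 min, among them Os10g0391400 (2.71, adjusted p = 0.025) and Os03g0181100 (2.23, adjusted p = 0.0285). This was the time with the most such members, with 1 of 14 past at 30 min (Os10g0391400, adjusted p = 0.0337) and 0 of 14 at 120 min in limma (lowest adjusted p = 0.0558). For the members past the test, these changes argue against a constant dye effect as the whole cause. They share the same 2 arrays of 0 min, however, and over all genes 0 passed the change of the ratio. The list had also been flagged by this same change. A constant dye effect stays possible as a part of the cause, and in the members with 0 such changes. Another candidate explanation is that the wild-type leaves at 0 min were further into the early wound response. Early genes were taken as those at least 2 log2 units higher at 30 than at 120 min in the mutant, without the JAZ list and RERJ1. A rise from 0 min was not required, so genes that only fell by 120 min can be among them. The 707 early genes had a median 0 min ratio of -0.071 (SD 0.536; 0.056 on replicate 1 and -0.168 on replicate 2), against -1.18 for the JAZ list. Of these genes 5.8% lay at -1 or less against 0.871% of other genes, and 1.13% at 1 or more against 0.36%, so that part of the excess is wider scatter. This explanation stays open. A lower resting level of JAZ transcripts in the mutant stays open too, as untested, since 2 replicates at 0 min cannot tell it apart from differences in handling.

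Across the 4 times, 229 genes lay above or below wild type (56 above, 173 below). Dye effects of single probes could produce such ratios, but the share of genes with other probes whose sign was the same was 1 (84 of 84 genes), with a median size of 0.944 relative to the tested probe. The rest of the 229 genes had no other probe past the filter and were not covered. A dye effect shared by all probes of a gene would give the same sign, so the comparison cannot exclude it. Blocks of neighbouring genes that differ between the line and wild type may account for part: 20 pairs of genes with the same direction and different descriptions lay within 5 places in locus order, against a median of 7 and a highest of 18 in 1000 random draws. The draws placed genes at random, so they cannot tell such blocks apart from neighbours that are regulated together. On chromosome 4, which carries RERJ1, 34 genes were found against 20.2 expected (one-sided hypergeometric test over 12 chromosomes, adjusted p = 0.0226). That test takes genes as independent, which genes in such blocks are not, so its p can be too small. The effect of the insertion itself stays open.

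The 75 wound-induced genes with a lower response in the mutant at an unadjusted p might come from differences between arrays that raise and lower ratios alike, since 48 wound-induced genes had a higher response by the same measure, against a simulated median of 6. They might also come from errors in the wild-type signal that enter both criteria. With genes induced on the slide of replicate 1 and the ratio change read on the other, 225 were lower and 144 higher (a ratio of 1.56). The other way round 192 were lower and 207 higher (0.928). An excess of lower changes thus appeared in 1 direction and was absent in the other. The test covered all genes 2-fold up in wild type on 1 slide, not the 75 genes alone. An effect of RERJ1 on the 75 genes cannot be told apart from array differences.

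Probes for microRNA precursors drew attention as a signal outside the gene tests: 4.12% of 510 such probes were well above background in both channels of all arrays, against 0% of 24 random or artificial probes. With 24 probes a share of this size can be missed, so the comparison does not separate the 2 kinds of probe.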

How the results depend on the processing

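The alternatives with 30 min as the baseline, without the 0 min arrays and for genes below wild type at the same time were chosen after the data were seen; the others before. Under the alternatives run, wild-type and mutant wound responses kept their counts within 1.5 times, except with no fold minimum (wild type 4526, 10794 and 11189 at 30, 60 and 120 min; mutant 4725, 11462 and 12155) and with the processed intensities (mutant 2577 at 30 min). Ratio counts moved more. At 0, 30, 60 and 120 min they were 47, 241, 354 and 412 with median centring and 145, 155, 187 and 299 with the replicate block. With no fold minimum 118, 181 and 559 genes passed at 30, 60 and 120 min, and 21 at 30 min with the processed intensities and with the deposited log ratios. A rule of 2-fold in both replicates without a test gave 116, 120 and 129 at 0, 30 and 60 min and 23, 60 and 69 for the ratio change. It gave 42 for wound-induced genes whose ratio fell, where the adjusted and unadjusted definitions become the same rule. The unadjusted count of 75 became 185 with the processed intensities, 141 with the deposited log ratios, 40 with median centring and 43 with the strict filter. The count of 81 below wild type became 37, 26, 137 and 210 with the processed intensities, the deposited log ratios, the replicate block and no fold minimum. With 30 min as the baseline 1 gene passed the ratio change at 120 min and without the 0 min arrays 1 passed the F test, in both cases Os07g0641400, a hypothetical protein chosen after its values were seen. Fewer genes pass a fold minimum by construction; otherwise the cause was not tested.

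Median centring turned the sign of the median of the ribosomal protein list for the ratio (0.231, 0.296, 0.337 and 0.42 at 0, 30, 60 and 120 min) and, without passing the test, for its change at 30 min (0.055) and of the markers of dividing cells at 120 min (0.133, adjusted p = 0.965); the cause was not tested. Leaving out 1 array reversed others, the lone array of a time being assumed to vary like the other groups. Over the arrays of 120 min (without replicate 2, then without replicate 1) the ratio at 120 min ranged from -0.024 to 0.45 for photosynthesis and from 0.018 to -0.14 for ribosomal proteins, and its change from -0.075 to 0.556 and from 0.088 to -0.067. For the change at 30 min, WRKY factors ranged from 0.023 (without replicate 1 of 0 min) to -0.177, protease inhibitors from 0.115 (without replicate 2 of 0 min) to -0.171 and ribosomal proteins from 0.017 (without replicate 2 of 30 min) to -0.117. The cause was not tested.

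Leaving out each array in turn gave 1750 to 2019, 4551 to 5112 and 4645 to 5483 genes for wild type and 1453 to 1720, 4034 to 4599 and 4610 to 5051 for the mutant. The ratio gave 9 (without replicate 1 of 60 min) to 97 at 0 min, 1 (without replicate 1 of 30 min) to 50 at 30 min, 1 (without replicate 1 of 60 min) to 59 at 60 min and 3 (without replicate 2 of 120 min) to 203 at 120 min, each highest without replicate 1 of 0 min. Its change gave 0 to 10, 0 to 6 and 0 to 6 and the F test 0 to 8, again highest without that array. Dependent genes were 0 to 1 (without replicate 2 of 120 min), 70 (without replicate 2 of 60 min) to 163 at an unadjusted p, and 12 (without replicate 2 of 120 min) to 90 below wild type. The RERJ1 ratio ranged from -6.53 to -2.83, -2.71 to -2.52, -1.58 to -1.40 and -1.51 to -1.08 at 0, 30, 60 and 120 min. With the replicate block RERJ1 passed at 0 min (-4.68, adjusted p = 0.0364), as did its wild-type change at 30 min. Beyond these and the lists named beside their results, the block lifted the change of the ribosomal list at 60 min past the test (adjusted p = 0.0328; adjusted p = 0.982 with an estimated correlation) and changed no other list call. That ribosomal change also passed with the strict filter and the mean of a gene's probes (adjusted p = 0.0469 and 0.0499) and without replicate 1 of 60 min (adjusted p = 0.000484). Over all alternatives, 6199 list results kept their call (past the test or not past it, in the latter case whatever the sign), 112 newly passed and 111 no longer did, some of these with a median of the other sign; 13 reversed. Signal over background limits what can be seen: 8972 of 41908 probes were too dim to test.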

Other observations

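The genes in this part were chosen after their values were seen, and the microRNA tests were added after the data were seen. A pair of annexin genes, whose proteins bind calcium and membranes, lay below wild type past the threshold at 0, 30 and 60 min: Os05g0382600 (-1.51, -1.28 and -1.51) and Os05g0382900 (-1.15, -1.03 and -1.31). At 120 min they were lower too (-0.998 and -0.784, adjusted p = 0.0134 and 0.0209 in limma) but missed the fold minimum. An RNase H domain gene (Os10g0458700) lay below at all 4 times (-1.39, -1.37, -1.20 and -1.48). In all, 8 genes passed at 4 times and 15 at 3 times.

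Of 73 microRNA precursor probes tested, adjusted over these alone with limma, those of osa-miR398a, a microRNA that targets copper superoxide dismutases, were lower in the mutant at 120 min (3' part -2.97 ± 0.438, adjusted p = 0.036; 5' part -2.30 ± 0.392, adjusted p = 0.0391). The 3' part of osa-miR528 fell in wild type at 60 min (-1.12, adjusted p = 0.0307) and 120 min (-1.14, adjusted p = 0.0416) and in the mutant at 120 min (-1.09, adjusted p = 0.00968). The 5' part of osa-miR419 fell in wild type at 60 min (-1.70, adjusted p = 0.0347) and in the mutant at 120 min (-1.55, adjusted p = 0.0318), and the 3' part of osa-miR172c rose in the mutant at 60 min (1.095 ± 0.104, adjusted p = 0.00346). These probes read precursors and other transcripts of the locus, and mature microRNA was not analysed here.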
